A study of Drosophila melanogaster with 3 samples.

How the data were processed

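Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of both sexes, 0 to 24 h old, from a transgenic line carrying CG9727 fused at its C-terminus to enhanced GFP. The fusion protein was precipitated with an antibody against GFP after sonication, per the labels. The 3 samples form 1 group, and the labels number them as biological replicates 1, 2 and 3. Nothing in the labels says whether the embryos came from separate collections, so the spread between replicates may in part be technical. Reads from the control named in the labels and from other lines are not analysed here. A control enters the values only through the authors' peak lists, described next, and no precipitate without the fusion is compared.

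The analysis starts from peak lists. Per the file descriptions, the authors made a relaxed list for each replicate from its alignment and 1 control file, a pooled relaxed list from the 3 alignments and the same control, and a thresholded list by irreproducible discovery rate (IDR) from those 4 lists, each on the dm6 and the dm3 genome builds. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. Each deposited peak carries the authors' signal value, a value on the −log10 scale of q, and the position of its summit. Signal was used only to rank and describe peaks inside a list. Other deposited columns (coordinates and summit offsets) were used as the authors gave them. Read counts are not part of these lists, so depth per sample is unknown from them, and no counting error on signal could be given. The relaxed dm6 lists held 30000 peaks each, which is a limit of the lists and not a measure of depth.

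Peak coordinates refer to dm6 unless dm3 is named, and all printed positions count from 1. Gene models came from Ensembl release 115 on the same assembly, and sequence from the RefSeq copy of that assembly. Of 17415 genes with the same name in the Ensembl and RefSeq annotations, 17413 had identical positions, and every dm6 peak ended inside its chromosome arm. Coordinates of dm3 peaks were never converted. Genes on the arms 2L, 2R, 3L, 3R, 4 and X were used, 18164 in all with 23998 transcription start sites (TSSs), and transposable elements annotated as genes were left out.

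A peak was represented by its summit. An IDR peak counted as recovered in a replicate when a summit among that replicate's 7896 strongest peaks, as many as the IDR list holds, lay within 100 bp. Rank agreement was Spearman's rho of signal across IDR peaks matched within 100 bp in the complete replicate lists. A gene counted as bound when an IDR summit lay within 500 bp of any of its TSSs. A summit was assigned to the first of these classes that applied: TSS within 500 bp, 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron, intergenic. The promoter share was compared by Fisher's exact test with the 19812 pooled peaks that overlap no IDR peak.

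Lists of 29 gene groups and 27 sequence motifs were written before the data were examined, as were the tests and the main alternatives. Protein-coding lists were tested against all other protein-coding genes and non-coding lists against genes of other types, by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 29 lists. After the files were seen, 17 older symbols were matched to current ones by name. Motif matches on either strand within 50 bp of the summit were compared with windows of equal width 500 bp to either side, by an exact McNemar test with adjustment over the 27 motifs. The share in the flanks is the mean of both sides, and the test used 1 side drawn at random per peak. Words of 7 bases were found in odd-ranked peaks by their excess over flanks and measured in even-ranked peaks, with a pseudocount of 1 on each count. A TSS belonged to a head-to-head pair when a protein-coding TSS of another gene diverged from it within 1 kb. Distal peaks had no TSS within 2 kb. Adjusted p-values under 0.05 were called.

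Peaks, genes and motifs are not replicates, so these tests describe where the peaks of 1 joint list fall. The error of each share comes from the 3 replicates, as the mean ± SD over the 7896 strongest peaks of each. The genes named in the text follow a rule set in advance: CG9727, the genes nearest to the 25 peaks of highest signal, up to 4 bound members with the strongest peaks and up to 2 unbound members in alphabetical order from each list called, and every homeotic gene. A gene that this rule selects is not reported here. Other genes are said to be chosen after their values were seen.

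Alternatives changed the matching distance, the TSS window, the number of peaks, the background and the build, left out each replicate, or used a replicate alone. After the data were seen, base-pair-preserving shuffles of the summit windows and the assignment of each peak to its nearest TSS only were added. Motif calls against shuffles compare the summit windows with the first of 10 shuffles by Fisher's exact test. The settings of 3 later tests were changed or fixed after a first run. The bound for AT-rich motifs was set at a weak-base fraction of 0.8 or more, which moved the Mef2 site into that group. In the coding exon test, 5′ UTR positions were left out so that it counts as the classes do. The search for 8-base words in odd-ranked peaks was set up after such words had been seen over all peaks, so the even-ranked peaks were not untouched. Leaving out gene names that end in L or T was also decided then. The alternative that matched genes on their number of TSSs used random draws of genes within strata. Exact intervals are Clopper-Pearson 95% intervals and cover counting error only.

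Functions were tested on simulated data. In 7896 simulated peaks a planted promoter share of 16.0% was measured as 16.0%, and a planted list with 80% of members bound was measured at 80%. The planted genes were isolated and had a single TSS each, so shared promoters and genes with several TSSs were not covered. Of 200 random lists of 50 genes, 4 had an unadjusted p under 0.05 and 0 passed after adjustment. A word planted in 10% of the windows raised its share by 9.76 percentage points. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.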

Results

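CG9727 fused to enhanced GFP was mapped by ChIP-seq with an antibody against GFP in whole embryos collected between 0 and 24 h. The data comprised 3 biological replicates of 1 group, with no second group to compare, so the design asks where in the genome the fusion protein was recovered and how far the replicates gave the same sites. The thresholded list held 7896 peaks on dm6, all on the 6 main chromosome arms, with a median width of 504 bp. Read depth is unknown from these lists.

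CG9727 itself (FBgn0037445, 3R 6449944 to 6456676, minus strand) had no thresholded peak at either of its TSSs. The nearest IDR summit lay 6474 bp from its closest TSS. Upstream of the gene, a weak peak at 3R 6460627 to 6461130 ranked 21139 of 30000 in the pooled relaxed list, and weak peaks there appeared in the relaxed lists of replicates 1 and 3.

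The strongest sites were shared by the replicates. The peak of highest signal lay in an intron (2L 480508 to 481414) and ranked 2, 1 and 1 in replicates 1, 2 and 3. The nearest TSS, 1367 bp away, belonged to cbt, the gene of the zinc finger protein Cabut. This peak was followed by those at the px promoter (2R 22514010 to 22514586) and in an intron nearest to a TSS of CG11050 (2L 6612345 to 6613027). Both were among the top 3 of every replicate. Of the 7896 IDR peaks, 6582 (83.4%), 6272 (79.4%) and 6743 (85.4%) were recovered among the strongest peaks of replicates 1, 2 and 3, a mean of 82.7% ± 3.03 (SD, n = 3). All 3 replicates recovered 4936 peaks (62.5%) and none recovered 114 (1.44%). The IDR list was made from these replicates, so part of this recovery is built in. Compared directly, 69.9% to 74.3% of the 7896 strongest peaks of a replicate had a summit within 100 bp among those of another. Across peaks, signal ranks gave a Spearman's rho of 0.775 between replicates 1 and 2, 0.813 between 1 and 3 and 0.830 between 2 and 3, a description across peaks that are not independent. Ranking by the authors' −log10 q in place of signal lowered the mean rho from 0.806 to 0.347.

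Among the 25 peaks of highest signal, 15 lay within 500 bp of a TSS, 8 in introns and 2 in non-coding exons. Promoter peaks of this set included those of Chro, which encodes the chromosomal protein Chromator (3L 22878650 to 22879170, 82 bp from the TSS), CG14100, Ugalt, the gene of a UDP-galactose transporter, Fkbp14, Tina-1, gish, which encodes a casein kinase, CG1888, CG13921, CG9147, larp and ph-p, a Polycomb group gene. The promoters of lncRNA:CR44339 and lncRNA:CR31840 and the Art3 promoter, at 3R 15229287 to 15229774 beside mRpS10, also belonged to it. Besides cbt and CG11050, intronic peaks lay nearest to TSSs of Trl, which encodes the GAGA factor (3L 14759239 to 14759845, 1527 bp from a TSS), Lk6, CG32772, CG9663, HmgZ and Tlk. The peaks at rank 4 and rank 10 were separate summits of 1 interval (X 12750691 to 12751736), both nearest to a TSS of lncRNA:CR44619. The summit at rank 4 had no replicate 2 summit within 100 bp.

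Binding was concentrated at promoters and nearly missing from coding sequence. A TSS lay within 500 bp of 3544 IDR summits (44.9%), against 25.4% of the pooled peaks outside the IDR list and 14.0% of random positions. Introns held 36.3% of summits and intergenic sequence 16.4%. Coding exons away from promoters held only 14 summits (0.177%), against 4.74% of the pooled peaks outside the list and 13.5% of random positions. The replicates gave a promoter share of 45.1% ± 1.69 and a coding exon share of 0.228% ± 0.0380 (SD, n = 3). The odds of a promoter position were 2.39 times those of the weaker pooled peaks (Fisher's exact test across peaks, p = 1.91e-212). With the peaks ordered by signal, the promoter share was 58.3% among the 789 strongest and 39.5% among the 790 weakest. Median signal in the IDR list was 302 for promoter peaks and 261 for distal peaks, a ratio of 1.16, and the replicates gave 1.09, 1.25 and 1.17.

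Summits at promoters mostly lay just upstream of the TSS. Their median position was −103 bp, with quartiles at −208 and −12 bp, and 77.7% lay upstream. Within 100 bp of the TSS were 39.2% of them.

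**Figure D1:**
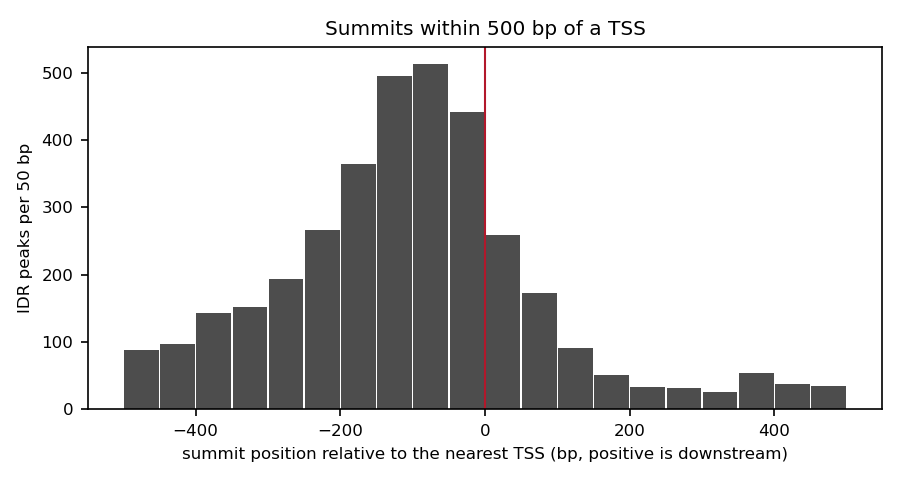
Number of IDR peaks per 50 bp (vertical axis) by the position of the summit relative to the nearest TSS in bp (horizontal axis), for the 3544 peaks with a TSS within 500 bp. The red line marks the TSS, and the bars are highest on its upstream side, around the median of −103 bp.

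An IDR summit lay at the promoter of 3770 of 13945 protein-coding genes (27.0%, and 27.1% ± 0.710 over replicates). Cytoplasmic ribosomal protein genes stood out. Of 85 such genes, 73 were bound (85.9%, replicates 87.1% ± 2.35, odds ratio 16.7, adjusted p = 1.99e-28 by Fisher's exact test). RpS27, RpL7 and RpL41 were among those with the strongest peaks, at ranks 94, 97 and 178. RpL10 and RpL10Aa were not bound. Mitochondrial ribosomal protein genes were bound in 39 of 73 cases (53.4%, replicates 53.4% ± 4.94, exact adjusted p = 7.87e-06), with peaks at mRpS10, mRpL41, mRpS23 and mRpL23 and none at mRpL1 or mRpL10. The aminoacyl-tRNA synthetases, which charge tRNAs, had 16 of 35 genes bound (45.7%, replicates 44.8% ± 3.30, exact adjusted p = 0.0394), among them IleRS, GluProRS, AspRS and SerRS but not AlaRS-m or AsnRS-m.

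Insulator and promoter factors and Polycomb and Trithorax group genes were bound more often than other coding genes. The list of insulator and promoter factors had 17 of 28 genes bound (60.7%, replicates 59.5% ± 7.43, odds ratio 4.19, exact adjusted p = 0.000599). It included Chro, Cp190, which encodes an insulator protein, and Dref and M1BP, which encode the factors known to bind the DRE and Motif 1 promoter elements. Clamp and Elba2 were not bound. Polycomb and Trithorax group genes were bound in 24 of 41 cases (58.5%, replicates 56.9% ± 2.82, odds ratio 3.83, exact adjusted p = 8.60e-05). Their strongest peaks lay at ph-p, brm, which encodes the Brahma remodelling ATPase, E(z), which encodes the methyltransferase of histone H3 lysine 27, and Trl, while Bap111 and Bap55 had none.

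Cell division, splicing and signalling lists were also bound more often than other coding genes. DNA replication and cell cycle genes reached 24 of 52 (46.2%, replicates 46.8% ± 2.94, exact adjusted p = 0.0111), including CycE, RnrS, Dp and Mcm2 but not Cdc45 or Cdk2. Spliceosome genes reached 18 of 38 (47.4%, replicates 46.5% ± 3.04, exact adjusted p = 0.0189), including U2af50, Sf3b6, SC35 and snRNP-U1-C but not Brr2 or Bx42. Genes of the Notch, Wnt, Hedgehog, EGFR, JAK-STAT and Hippo pathways reached 26 of 61 (42.6%, replicates 43.2% ± 5.27, exact adjusted p = 0.0189). Peaks lay at spi and aos, which encode an EGFR ligand and an EGFR inhibitor, sgg, which encodes the GSK3 kinase, and yki, the Hippo pathway coactivator, with none at Axn or Delta.

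In total 8 of 29 lists were bound more often than other genes, with a share above that of all coding genes in each of the 3 replicates, and several calls rested on the settings. Ribosomal protein genes stayed at 85.9% when each peak was given only to its nearest TSS, an alternative chosen after the data were seen. Mitochondrial ribosomal protein genes then had 23.3% bound, aminoacyl-tRNA synthetases 28.6% and spliceosome genes 31.6%, none of them called. Among the 3948 strongest peaks the synthetase, replication, spliceosome, Polycomb and Trithorax, and signalling calls were lost. The synthetase call was also lost in replicate 1 and in replicate 2 alone and at 1 kb, the spliceosome call at 1 kb and the replication call at 200 bp. The signalling call was lost at 200 bp, in replicate 3 alone and with genes matched on their number of TSSs. Over all alternatives the adjusted p, by exact or permutation tests, ran from 1.59e-07 to 0.700 for mitochondrial ribosomal proteins, 0.00988 to 0.429 for synthetases and 0.00241 to 0.202 for replication. It ran from 0.00447 to 0.190 for the spliceosome, 1.69e-05 to 0.181 for Polycomb and Trithorax genes, and 0.000232 to 0.201 for signalling, again by exact or permutation tests.

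Cuticle, chemosensory, neuronal terminal differentiation and spermatogenesis genes were bound less often than other coding genes. Cuticle protein genes had 1 of 122 bound (0.820%, odds ratio 0.0220, exact adjusted p = 1.03e-14), which was Cpr67Fb, with none at Acp65Aa or Ccp84Aa. Chemosensory receptor and odorant-binding protein genes had 3 of 230 bound (1.30%, exact adjusted p = 3.42e-26), which were Obp99b, Or88a and Obp83g, the last with a matching summit in replicate 2 alone, and Gr10a and Gr10b were among those without a peak. Gr10a and Gr10b lie side by side on X, and neighbouring members of any list are not independent. The tests counted each gene separately, so the cuticle and chemosensory p-values may be smaller than the evidence warrants. Neuronal terminal differentiation genes had 2 of 31 bound (6.45%, exact adjusted p = 0.0180), fne and Shab, while ChAT and DAT, which encode choline acetyltransferase and the dopamine transporter, had no peak. Spermatogenesis genes had 1 of 31 bound (3.23%, exact adjusted p = 0.00282). That list member was Ssl1, and whether it is specific to spermatogenesis was not checked. The peak was the one between Ssl1 and Chro, 187 bp from the Ssl1 TSS and 82 bp from that of Chro. With the nearest TSS only, 0 of 31 members of this list were bound. Mst77F and Mst84Da had none. The neuronal call was lost with a window of 1 kb, in replicate 3 alone, with the nearest TSS only and among the 3948 strongest peaks, and the spermatogenesis call among those peaks.

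Histone, tRNA, and snRNA and snoRNA genes were also bound less often. Histone genes had 2 of 113 bound (1.77%, exact adjusted p = 2.27e-12), His2Av and His4r, and the repeated His1:CG31617 and His1:CG33801 copies had none. Copies that lie together, such as these on 2L starting at 21421855 and 21416953, are not independent. The test counted each as a separate gene, so this p-value is smaller than the evidence warrants. Genes for tRNAs had 20 of 290 bound (6.90%, against 23.1% of genes of other types, exact adjusted p = 2.27e-12), with the strongest peaks near tRNA:Tyr-GTA-1-8, tRNA:Phe-GAA-1-2, tRNA:Gly-GCC-1-9 and tRNA:Trp-CCA-2-2 and none near tRNA:Ala-AGC-1-1 or tRNA:Ala-AGC-2-1. The peak near tRNA:Gly-GCC-1-9 is the same as that near tRNA:Trp-CCA-2-2, and such neighbours were counted separately here too. With the nearest TSS only, 7 of 290 were bound, again called lower. Genes for snRNAs and snoRNAs had 29 of 301 bound (9.63%, exact adjusted p = 1.28e-08). Their strongest peaks lay near snoRNA:U49:66Da, snoRNA:Or-CD11a, snoRNA:Or-aca5 and snoRNA:Psi28S-2949, with none near scaRNA:MeU1:95C-A24 or scaRNA:MeU1b-A234. The summits near snoRNA:U49:66Da, snoRNA:Or-CD11a and snoRNA:Or-aca5 each lay 494 bp from the TSS, close to the limit of 500 bp. The peak near snoRNA:Or-aca5 is the same as that near snoRNA:Psi28S-2949. With the nearest TSS only, 13 of 301 were bound, again called lower, so some of the 29 had only peaks nearer to another TSS. By type, 18.8% of snRNA and 8.55% of snoRNA genes were bound. Other non-coding types were also low, with 9.48% of ncRNA genes, 4.48% of pseudogenes and 0 of 99 rRNA genes. Most genes tested against were protein-coding, so these low shares were not particular to the tRNA, snRNA and snoRNA lists. Reads from repeated gene copies can be lost in alignment, so the histone and tRNA shares are uncertain, and the snRNA and snoRNA call was lost with a window of 1 kb (24.9%). The tRNA share also depended on the window, with 2 of 290 bound within 200 bp and 40 of 290 (13.8%) within 1 kb, called lower at both.

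The other 14 lists were not called at the main settings. Oxidative phosphorylation genes were bound in 22 of 84 cases (26.2%) and proteasome genes in 13 of 48 (27.1%), close to the 27.0% of all coding genes. Patterning genes gave 9 of 34 for segmentation, 9 of 27 for dorsoventral patterning and 16 of 39 for neurogenesis. Markers of cell types gave 7 of 32 for muscle, 11 of 23 for germ line and pole cells (exact adjusted p = 0.0565) and 4 of 23 for haemocytes and fat body. The remaining lists gave 30 of 79 for RNA polymerase II and general transcription factors (exact adjusted p = 0.0564), 10 of 20 for autophagy, 10 of 23 for the nuclear pore, 11 of 27 for heat shock genes (called higher with the nearest TSS only, exact adjusted p = 0.0391) and 9 of 47 for immune genes. Under other settings fixed in advance some of these were called. RNA polymerase II and general transcription factors were called higher at 200 bp, at 1 kb, in replicates 1 and 2 alone and with genes matched on their number of TSSs. Autophagy genes were called higher at 200 bp, among the 3948 strongest peaks and in replicates 1 and 2 alone. Neurogenesis genes were called higher in replicate 1 alone, germ line and nuclear pore genes in replicate 2 alone, and immune genes were called lower at 200 bp. Of the 8 homeotic genes, lab, Dfd and Antp had a summit within 500 bp of a TSS, at ranks 5116, 2428 and 4065, and pb, Scr, Ubx, abd-A and Abd-B had none.

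**Figure D2:**
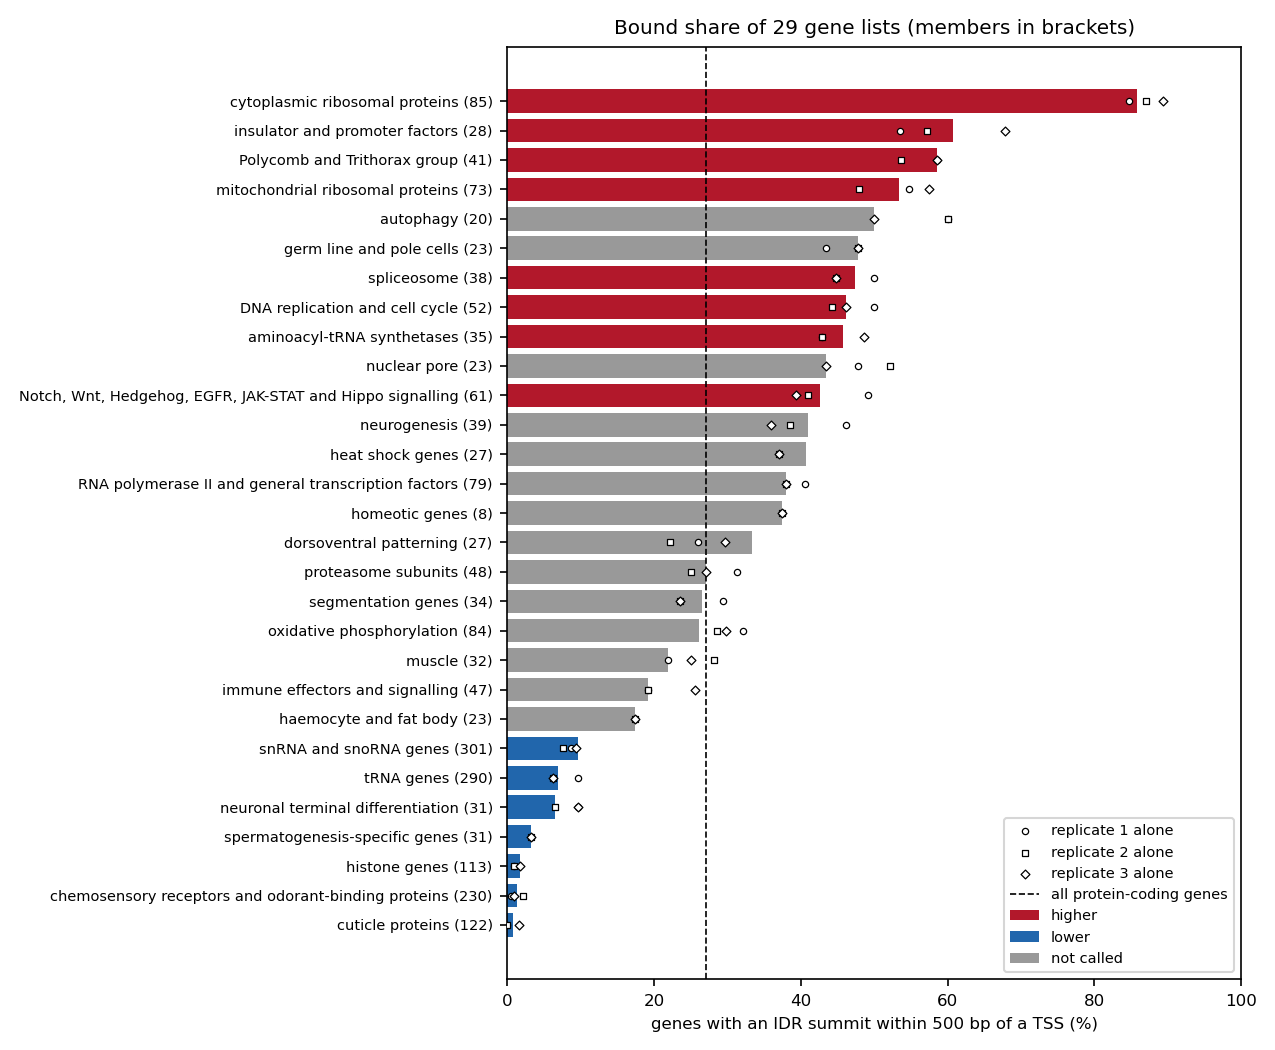
Share of genes with an IDR summit within 500 bp of a TSS, in percent (horizontal axis), for each of the 29 gene lists (vertical axis, with the number of members). Bars give the IDR list, red where called higher, blue where called lower and grey where not called, and open symbols give the 3 replicates alone. The dashed line is the 27.0% of all protein-coding genes, and ribosomal protein genes stand farthest above it at 85.9%.

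Summits carried promoter and insulator elements more often than their flanks. The DRE, TATCGATA, occurred within 50 bp of 1.75% of summits and in 0.209% of flanking windows, and Motif 1, GGTCACAC, in 1.05% and 0.196% (adjusted p = 1.42e-24 and 3.09e-14, exact McNemar test across peaks). In the replicates these shares were 1.72% ± 0.0698 and 1.09% ± 0.0193 (SD, n = 3). The core sites of the insulator proteins CTCF (0.887% against 0.298%) and Su(Hw) (0.253% against 0.0760%) and the CGATA site of BEAF-32 (14.8% against 11.8%) were higher as well. CGATA is part of the DRE word, so its excess includes that of the DRE and was not measured apart from it. Among promoter peaks alone, compared with unbound promoters at the same distance from the TSS, DRE (3.70% against 1.33%), Motif 1 (2.20% against 0.790%) and the CTCF core (0.847% against 0.254%) were again higher, with adjusted p = 3.71e-09, 9.42e-06 and 0.00398 by Fisher's exact test. The Su(Hw) difference did not pass there (exact adjusted p = 0.383). Bound and unbound promoters may differ in gene type, as 27.0% of protein-coding and 9.48% of ncRNA genes were bound. How far gene type contributes to the motif differences from unbound promoters was not tested.

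The other 6 motifs called higher at summits were AT-rich. The TATA box occurred at 8.33% of summits and in 3.44% of flanks, the Mef2 site at 6.69% and 2.72%, the homeodomain core TAATTA at 9.85% and 5.59%, the GATA site at 17.5% and 11.5%, Ohler motif 6 at 4.17% and 2.03%, and the A tract at 7.36% and 5.97%. Sites of GAGA factor (1.51% against 2.88%), Zelda (0.431% against 0.703%), Twist (3.63% against 5.17%), Pho (3.88% against 4.52%), Grainyhead (2.61% against 4.00%) and E2F (1.36% against 1.99%) and the CA repeat (0.583% against 2.01%) were lower. In all, 11 motifs were called higher and 7 lower of 27. Base-pair-preserving shuffles of the same windows, chosen after the data were seen, held the TATA box in 8.06%, the Mef2 site in 6.55%, TAATTA in 11.9% and the GATA site in 18.5%, so these 4 motifs were not called above shuffled sequence, and TAATTA was called below it. Of the motifs lower than in flanks, the GAGA factor and Pho sites and the CA repeat were called above shuffled sequence, and the E2F and Zelda sites were not called. The Zelda call against flanks was also lost in each replicate alone, the Su(Hw) call in replicate 2 alone and the Pho call in replicate 3 alone. Against unbound promoters only the Twist site of the 7 stayed lower, with the calls of GAGA factor, Zelda, Pho, Grainyhead, E2F and CA repeat lost, and the Initiator was called lower (8.07% against 11.99%). Of the AT-rich motifs, the TATA box (8.44% against 6.63%), the Mef2 site (6.72% against 4.32%), TAATTA (9.71% against 6.94%) and the GATA site (15.8% against 13.2%) were called higher there, and Ohler motif 6 and the A tract were not.

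**Figure D3:**
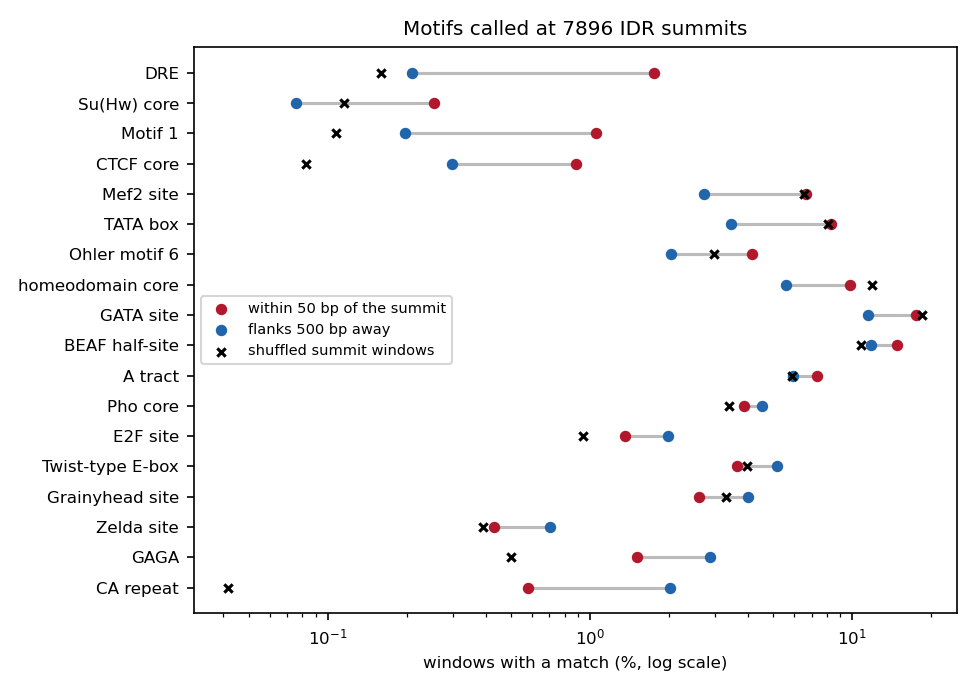
Share of windows with a match in percent on a log scale (horizontal axis) for the motifs called higher or lower (vertical axis). Red points are windows within 50 bp of the 7896 IDR summits, blue points the flanks 500 bp away and crosses the shuffled summit windows. DRE and Motif 1 lie above flanks and shuffles, while TATA box and Mef2 sites lie above flanks and close to shuffles, and the GATA site lies above flanks and below shuffles.

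The summits were local maxima of A+T content. Windows at IDR summits were 65.9% A+T against 56.3% in flanks, and the replicates gave 65.3% ± 0.212 (SD, n = 3). Distal summits were richer in A+T (67.2%) than promoter summits (64.7%), and unbound promoters at the same distance from the TSS had 59.4%. The leading 7-base words were all made of A and T. TTTAAAA occurred in 13.4% of even-ranked summit windows and 4.77% of flanks, a log2 ratio of 1.49, followed by AAAATAT (16.5% against 6.48%) and AAATATT (14.0% against 5.36%).

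**Figure D4:**
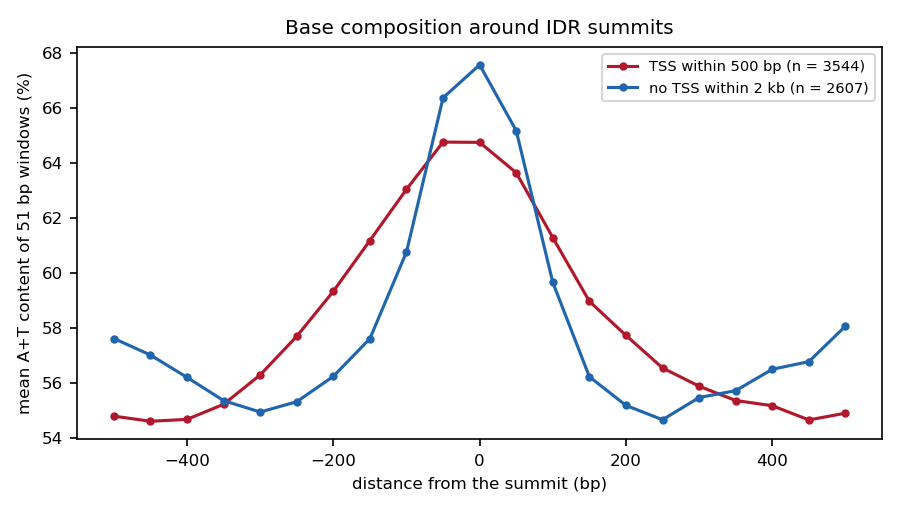
Mean A+T content of 51 bp windows in percent (vertical axis, not starting at 0) by distance from the summit in bp (horizontal axis), for 3544 promoter and 2607 distal IDR peaks. The promoter curve is highest 50 bp upstream along the reference strand, at 64.8% as at the summit itself, and the distal curve at the summit, at 67.6%, and at 300 bp upstream along the reference strand they stand at 56.3% and 54.9%.

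The large arms had similar mean densities of peaks, and the small chromosome 4 had few, as did the centromere-proximal 2 Mb of the large arms, a region chosen after the data were seen, with 25 peaks in all, 16 on 2L and 9 on X. The density ran from 53.7 per Mb on 2R to 63.5 per Mb on 3L, with 61.0 on X, and was 7.42 per Mb on chromosome 4, which held 10 peaks (replicates 9.64 ± 3.23 per Mb). On the X, 829 of 3309 protein-coding TSSs were bound (25.1%), and on the large autosomal arms 4068 of 16156 (25.2%). The odds ratio was 0.993 (p = 0.895, Fisher's exact test), and the difference over replicates was −0.542 ± 0.719 percentage points. With a window of 200 bp the odds ratio was 0.841 (exact p = 0.00120), and among the 3948 strongest peaks it was 0.857 (p = 0.00539), so a lower share on X was called under these settings. With a window of 1 kb and in replicates 1, 2 and 3 alone none was called.

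Promoters shared by diverging genes were bound more often than others. Of 4903 bound protein-coding TSSs, 2863 (58.4%) belonged to a head-to-head pair, such as those of Chro and Ssl1, against 3322 of 14704 unbound TSSs (22.6%). The odds ratio was 4.81, and 4.74 ± 0.152 over replicates (SD, n = 3). Since 1 peak can lie within the window of both TSSs of a pair, each peak was also given to its nearest TSS only, after the data were seen, and the odds ratio was then 2.06 (45.6% against 28.9%, p = 6.17e-72, Fisher's exact test).

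On dm3 the thresholded list held 7284 peaks, and the dm6 list held 8.40% more. The shares of the arms were close, for example 18.3% of dm3 peaks and 18.2% of dm6 peaks on X and 23.9% of each on 3R. Chromosome 4 held 5 dm3 peaks. Recovery of dm3 peaks was 83.3%, 79.9% and 86.0% in replicates 1, 2 and 3. Single peaks were not matched between builds.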

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

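In the relaxed dm3 lists, which no comparison above uses beyond the main arms, some peaks lay on heterochromatic or unplaced sequences. There were 13 in replicate 1, 90 in replicate 2, 29 in replicate 3 and 16 in the pooled list. Each was flagged for being above a fixed bound of 3, which is not a test. The sequence with the most was 3LHet in replicate 2, with 30 peaks, and XHet in replicates 1 and 3, with 12 and 15. The thresholded dm3 list held 0 peaks there, and no dm6 list held peaks outside the main arms. These sequence names are those of dm3, and coordinates were not converted. The dm6 lists therefore do not show whether the same sites had peaks on dm6. No explanation was tested.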

How the results depend on the processing

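Of 77 values of the main comparisons under settings fixed before the data were examined, 64 kept their side of the threshold, or stayed within the replicate spread or 1.5 times the count. Of 105 such values of single gene lists 18 lost the call and 87 kept it, and of 108 of single motifs 13 lost it, 1 reversed and 94 kept it. The 64 include mean recovery, promoter share and coding gene share with 1 replicate left out. By arithmetic such a mean cannot leave the replicate spread, so these values could not fail and test nothing. Mean replicate recovery was 90.1% with any overlap, 71.2% within 50 bp, 93.6% against lists of 2 times the length, 94.98% against complete lists and 96.6% for the 3948 strongest peaks. Mean rank agreement was 0.838 among those peaks and 0.347 by −log10 q, and ran from 0.775 to 0.830 with 1 replicate left out. The lists called higher numbered 4 among the strongest peaks. Against unbound promoters 8 motifs were higher and 2 lower, and against shuffles 11 and 4, which does not say that these are the motifs called against flanks. The leading 6-base word had a log2 ratio of 1.16. The X to autosome odds ratio was 0.841 within 200 bp and 0.857 among the strongest peaks, both past the threshold. The A tract reversed to 0.990 against unbound promoters. For all these changes the cause was not tested.

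Shuffled windows and the nearest TSS were settings chosen after the data were seen. Against the first shuffle the odds ratios reversed to 0.822 for the homeodomain core, 3.08 for GAGA, 1.30 for Pho and 23.1 for the CA repeat, each called. They were 0.914 for the GATA site, 1.38 for E2F and 0.954 for the TATA box, none of them called, and over all 10 shuffles the TATA box was slightly more frequent at summits (8.33% against 8.06%). The cause was not tested. Taking the 7896 strongest pooled peaks moved nothing, because these are the IDR list itself, and is not counted here. The number of replicates, 3 of 1 group, gives a spread but no test between conditions.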

Other observations

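The tests of mixed-composition motifs, of Ohler motif 6 and the A tract and of highly expressed genes, and all those using shuffles, the nearest TSS, words of 8 bases, arm ends or chromosome 4, were chosen only after the results were seen.

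The ribosomal protein genes without a peak fell into recognisable sets. Of the 12, chosen here after their values were seen, RpL10Aa, RpS10a, RpS15Ab, RpS19b, RpS28a and RpS5b are named as copies of other ribosomal protein genes. RpS3A lies on chromosome 4, 337359 bp from the nearest IDR summit. RpL5 and RpL21 on 2L, RpL10 and RpL15 on 3L and RpL38 on 2R lay 603028, 314211, 185332, 4357116 and 611915 bp from the nearest summit, all beyond the summit closest to the centromere on their arm. That summit was at 21933622 on 2L, 5128373 on 2R, 22910139 on 3L and 4214265 on 3R, with 38, 38, 41 and 14 coding genes beyond it. In the centromere-proximal 2 Mb of 2L and X, 7 of 83 and 4 of 67 coding genes were bound. The same span of 2R and 3L, with 10 and 9 coding genes and none bound, lies beyond the summits just given and adds nothing to them, and that of 3R holds no coding gene. Elsewhere on the 5 large arms 3754 of 13696 were bound (27.4%). On chromosome 4, 5 of 80 were bound (6.25%, odds ratio 0.177, Fisher's exact test, p = 3.24e-06). Poor alignment of reads there was not tested.

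Words of 8 bases were found in odd-ranked and counted in even-ranked peaks, for promoter and distal summits apart. At promoters the leading words were ATCGATAG, which overlaps the DRE, the DRE itself and Motif 1, in 3.76%, 3.70% and 2.02% of 1783 peaks against 0.168%, 0.191% and 0.107% after shuffling. At distal peaks CACTGAGA led (1.62% of 1297 peaks against 0.123%), followed in the order of the search by GCAAACAA, with a forkhead-like core, at 2.85% against 0.971%. Whether a word differs between promoter and distal peaks was not tested. Of the 47 distal summits with CACTGAGA, 63.8% had it in sequence soft-masked as repeats (exact 95% interval 48.5% to 77.3%), against 24.1% of all distal summit positions, so copies of repeated sequence stay an open explanation for this word.

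AT-rich motifs at the summits may reflect the base composition of the windows. Over the 6 AT-rich motifs called higher, the median ratio of the observed to the shuffled share was 1.03 ± 0.0275 (SD over 10 shuffles), so composition alone gives most of their frequency, while Ohler motif 6 and the A tract stayed above it (lower ratio 1.25) but were not called against unbound promoters. For the 5 other motifs called higher the median ratio was 9.76 ± 1.90, from 1.37 for the CGATA site and 2.20 for Su(Hw) to 9.76 for Motif 1, 10.8 for CTCF and 11.0 for DRE, so composition gave less than the share of each, by a small margin for the CGATA site. Bound promoter summits had 5.23 ± 0.2497 (SE) percentage points more A+T than unbound promoters at the same distance from the TSS. Bound windows were centred on their own summits, and unbound windows were placed at distances taken from bound promoters. At promoter peaks A+T fell from 64.8% at the summit to 59.3% and 57.7% at 200 bp to either side. The difference may therefore in part come from this centring. The unbound promoters were drawn from genes of all types without matching on gene type, so the difference may also in part be one of gene type. Whether the fusion prefers AT-rich DNA, or fragments of such DNA are recovered more readily, was not tested.

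The high share of bound ribosomal protein genes could come from recovery of all strongly and broadly expressed promoters. Oxidative phosphorylation and proteasome genes were set beside them, without names ending in L or T that often mark testis copies. Of 106 such genes 31.1% were bound (exact 95% interval 22.5% to 40.9%), far below 85.9%. That these genes are strongly and broadly expressed was assumed, as expression was not measured here. The comparison therefore cannot decide whether recovery rises with the strength of expression. Peaks of neighbouring genes do not account for the high share of ribosomal protein genes. With the nearest TSS only, that share was 4.29 times that of other coding genes. Background of the anti-GFP precipitation that favours certain open promoters stays open, as no precipitate without the fusion is analysed here. With 1 group in the design, no biological explanation was tested.

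The scarcity of summits in coding exons could follow from their lower A+T content or from the precedence given to promoters. Random positions matched to the summits on arm and A+T content lay in coding exons away from promoters in 5.48% of cases (exact 95% interval 5.24% to 5.74%), against 0.177% of summits. With promoter regions counted too, 36 summits lay in coding exons, 0.0674 times the share of matched positions. That comparison applied both controls at once, with 0.456% of summits (exact 95% interval 0.320% to 0.631%) against 6.77% of matched positions. Neither explanation, nor both together, was therefore enough. No biological explanation was tested.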
